A study of Homo sapiens with 6 samples.

How the data were processed

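Poly(A) RNA of 6 libraries was measured by sequencing with a directional kit: 2 libraries each of H9 cells given ASO-Ctr, sO-L1 or ASO-L1. The groups were taken from the labels, and the columns of the tables were matched to them by the group and replicate in each column's name. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.0, mapped to hg19 with TopHat2 2.0.13 and assigned to genes with featureCounts of Subread 1.5.0. The deposited counts are raw counts per gene symbol, with duplicate reads removed by the authors according to the table's name. The strand setting of the counting is not stated, so counts of antisense and overlapping genes are uncertain. The authors' deposited log2 table holds log2 normalized values after batch correction. The authors' deposited comparison table gives log2 fold changes and p-values of 1 comparison, ASO-L1 minus sO-L1, and its p-value adjustment is not stated. The sign of that comparison was settled against the deposited log2 table (correlation 0.996).

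The count table has 53807 entries, of which 92 are spike-in sequences, left out of library sizes and tests. Of the 53715 genes, 35175 had at least 1 count and 19156 passed filterByExpr (minimum count 10, minimum total 15). Library totals ranged from 18897936 to 67192937 counts, with 23837 to 29825 genes detected. Mitochondrial genes held 3.79% to 4.24% of the counts and the top 10 genes 4.47% to 4.73%. No pair of libraries was identical. A count of 0 stayed 0 in the fits, and the floor stated for it is the CPM of 3 counts.

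Counts were scaled by TMM (factors 0.983 to 1.02) and fitted with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, robust estimation, and group and replicate number in the design. All 6 libraries were in 1 fit, which left 2 residual degrees of freedom per gene before moderation, a median prior of 44.8 and a biological coefficient of variation of 0.0354. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 comparisons were ASO-L1 against sO-L1, ASO-L1 against ASO-Ctr and sO-L1 against ASO-Ctr. SE was the absolute log2 fold change over the square root of F. Levels are CPM.

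The replicate number entered the design before the data were examined, because the labels list a batch-corrected table among the study's outputs. The labels do not say that a number marks a shared batch, and there are 2 numbers, so the pairing is not established. Differences between replicates 1 and 2 had correlations of 0.329, 0.249 and 0.369 between groups, measured as a check. The mean of replicate 1 over all groups was also set against that of replicate 2. These means lay within 0.02 of each other for 82.6% of genes in the deposited log2 table, against 9.12% in log2 CPM. A correction by replicate number would leave such equal means, but they do not show that the numbers mark real batches. The fit without the replicate block gave far fewer calls, and its values stand beside the results.

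The 23 gene lists were fixed before the data were examined: the 8-cell, naive, core and primed pluripotency, PRC2, HOX, nucleolar, ribosomal protein and L1 silencing lists, 8 stress, metabolism and cell cycle lists, with cholesterol synthesis among them, 2 RNA quality lists and 5 cell type lists. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over all lists in a comparison. Members called were counted over all genes and adjusted over the list alone. Named genes were, by a rule fixed beforehand, the 8 with the largest change in each direction in the ASO-L1 comparisons and the 4 in sO-L1 against ASO-Ctr. They had to be called, have an average log2 CPM of at least 1 and the same sign in both replicates. Up to 4 members of each list with the smallest p were named in addition.

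The alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, no filter, a filter of CPM above 0.5 in 2 libraries, DESeq2 1.42.0, limma-voom, no replicate block, the 4 libraries of the groups compared, each library left out in turn, a fold of at least 2, adjusted p under 0.1, an estimated correlation and fry. A library left alone in its group was assumed to vary like the other groups. Thinning all libraries to the shallowest was added after the data were seen. The pipeline was tested on simulated data with 19156 genes: 61% of 1.5-fold and 78% of 2-fold changes were recovered in ASO-L1 against sO-L1, with 4 unchanged genes called and 1 of 100 unchanged lists at p under 0.05. In ASO-L1 against ASO-Ctr the values were 59% and 78%, with 5 unchanged genes called, and lists were not simulated. Simulated genes were drawn independently, with a replicate shift and the spread of the blocked fit. The simulation therefore cannot test the replicate block or the effect of correlation between genes. Estimated correlations in ASO-L1 against sO-L1 were 0.316 for the stress response, 0.383 for the cholesterol and 0.571 for the immediate-early list. The correlation of fold changes between comparisons was set beside 20 simulations of unchanged groups. Gene span, transcript length and GC content came from GENCODE 29 on another genome build, matched by symbol for 80.6% of the tested genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. The L1 element and the 8-cell genes with too few counts were not tested. Some genes that meet the naming rule are not reported here.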

Results

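RNA was sequenced from H9 cells, a human embryonic stem cell line in the primed state, 48 hours after transfection with 1 of 3 fluorescein-tagged oligonucleotides. LINE1 (L1) is a family of transposable elements with many copies in the human genome. The groups were a non-targeting antisense oligo (ASO-Ctr), a sense oligo of L1 (sO-L1) and an antisense oligo against L1 (ASO-L1), each at 25 nM. Tagged cells were sorted before RNA extraction. Per the labels' protocols all cells also received 0.7 uM ISRIB, a blocker of the integrated stress response, 5 uM emricasan, a caspase inhibitor, and 10 uM of a ROCK inhibitor, removed after 24 hours. The labels name mTeSR medium after transfection in 1 place and RSeT medium in another, so the medium at collection is not settled here. Each group had 2 libraries. Counts summed to 18897936 and 67192937 in ASO-Ctr, 34665403 and 60999413 in sO-L1, and 46223290 and 57899009 in ASO-L1 (replicates 1 and 2).

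The stated question is the role of L1 in the control of genes of the 8-cell stage of the human embryo. No gene of the count table names the L1 element, so the level of the target itself was not analysed here and the group labels were not checked against it. Adjusted p-values of genes are from edgeR's quasi-likelihood test with the replicate number as a block, and those of gene lists from camera with a preset correlation of 0.01, both with Benjamini-Hochberg adjustment. Values after a gene's name are log2 fold changes ± SE, with n = 2 libraries per group. The labels do not say that the replicates are separate cultures, so the spread between these libraries may be technical. P-values and SEs of the blocked fit use only the spread left after the shift between replicate numbers is removed, moderated across genes. The SDs of CPM include that shift, so these p-values do not cover them. No list passed in any comparison when camera used an estimated correlation, for which the design leaves 2 residual degrees of freedom. With fry, a self-contained rotation test, 0 of the 7 lists that camera called in ASO-L1 against sO-L1 passed, 3 of 7 in ASO-L1 against ASO-Ctr and 0 of 6 in sO-L1 against ASO-Ctr. Where a library was left out of a group being compared, that group had 1 library, which is assumed to vary like the other groups, so passes and losses there are not replicated tests. Floors cover counting error only, and a count of 0 allowed between 0.0446 and 0.159 CPM per library (3 counts).

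ASO-L1 against sO-L1 compares the antisense with the sense L1 oligo, the pair of the authors' deposited comparison table. The lists of the integrated stress response and of p53 targets were higher in ASO-L1, and the cholesterol synthesis list was lower, by camera at its preset correlation. All 3 calls were lost (adjusted p = 0.414, 0.414 and 0.573 with an estimated correlation), and 0 of 22 cholesterol genes were called without the replicate block. TAC1, the precursor of substance P, rose 4.41-fold, from 1.15 ± 0.0394 to 5.41 ± 2.25 CPM (mean ± SD, n = 2). ATF5, a transcription factor translated under stress, rose 3.8-fold, from 18.1 ± 3.21 to 69.7 ± 20.7 CPM. ARHGAP28 fell from 31.4 ± 1.01 to 9.83 ± 1.81 CPM. Of the 47 members of the 8-cell list only 9 could be tested, and none of these passed. ZSCAN4, LEUTX, DUXA and TPRX1 were not among the 9, so the tests do not speak for them.

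Among the genes with the largest increases by the rule fixed beforehand were ANXA1 3.38 ± 0.20, TAC1 2.14 ± 0.18, ATF5 1.93 ± 0.06, KLF4 1.86 ± 0.17, INHBE 1.80 ± 0.10, NEAT1 1.76 ± 0.12 and SOX21 1.76 ± 0.10. Their adjusted p-values lay between 2.8e-28 for ATF5 and 2.5e-08 for NEAT1. ANXA1 encodes a phospholipid-binding annexin, KLF4 a pluripotency transcription factor, INHBE an activin subunit, NEAT1 the long non-coding RNA of paraspeckles and SOX21 a neural SOX factor. ANXA1 and SOX21 lost their calls without the replicate block (adjusted p = 0.0548 and 0.0596), and the other 5 listed passed in that fit. The largest decreases were FAM189A1 -2.08 ± 0.14, ARHGAP28 -1.67 ± 0.08, TMEM179 -1.53 ± 0.15, IMMP2L -1.52 ± 0.18, TBX10 -1.33 ± 0.16, CTNNA2 -1.28 ± 0.12, FAM155A -1.24 ± 0.15 and COMMD1 -1.23 ± 0.10, with adjusted p-values from 7.2e-23 for ARHGAP28 to 1.6e-08 for FAM155A. CTNNA2 encodes a neuronal alpha-catenin, IMMP2L a mitochondrial inner membrane peptidase subunit, TBX10 a T-box factor and COMMD1 a regulator of copper handling. All 8 of these also passed without the replicate block (adjusted p = 7.9e-04 for ARHGAP28 to 0.0236 for FAM155A). Genes lower in ASO-L1 were long: their median genomic span was 48.7 kb, against 28.2 kb for genes higher and 27.2 kb for genes not called.

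In all, edgeR called 1982 genes higher and 2430 lower of 19156 tested, with a median absolute log2 fold change of 0.29 among them. Without the replicate block the counts were 175 and 177, with 3167 genes at an unadjusted p under 0.05, and 351 of these 352 genes were also called with it. The counts were 841 and 1110 without sO-L1 replicate 1, 925 and 1145 without ASO-L1 replicate 1, and 1531 lower without sO-L1 replicate 2. At least a 2-fold change was seen for 160 of the genes higher and 64 of the genes lower.

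**Figure D1:**
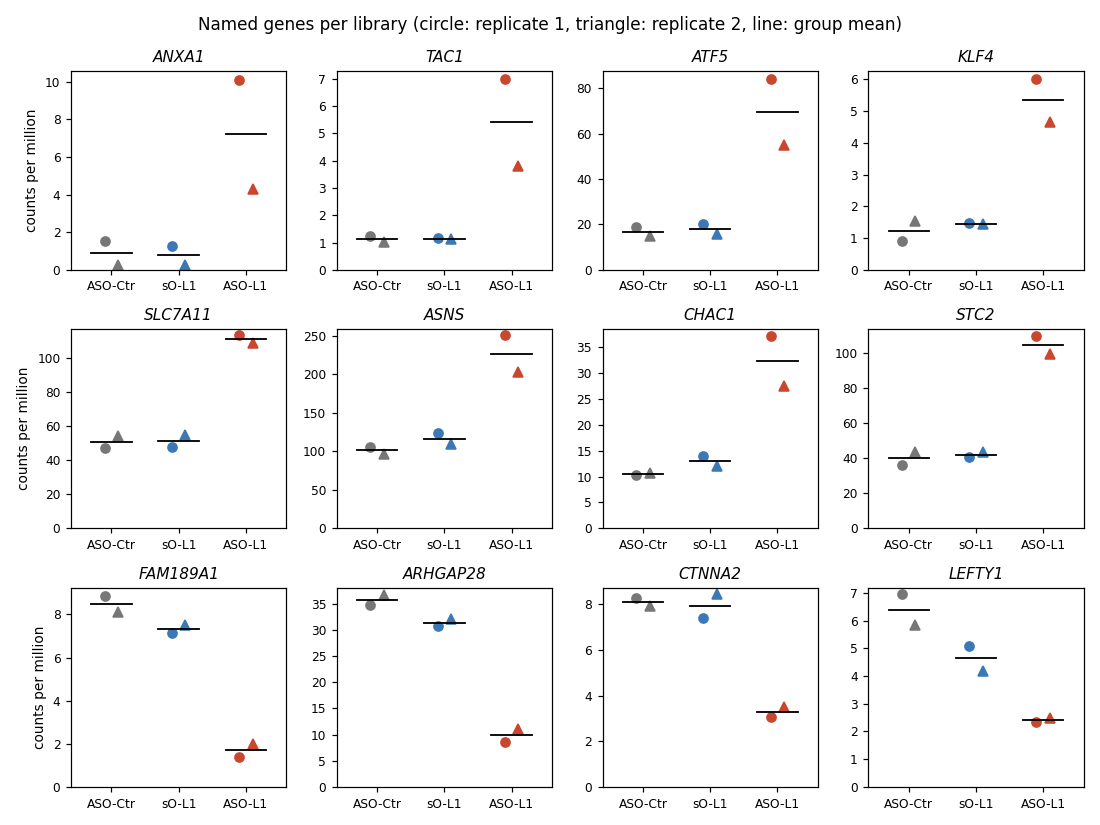
CPM (vertical axes, starting at 0) of 12 named genes in the 6 libraries, by group. Circles are replicate 1, triangles replicate 2 and lines the mean of 2 libraries. ATF5 lies at 84.3 and 55.1 in ASO-L1 (replicates 1 and 2) and at 14.8 to 20.3 in the 4 control libraries, and ARHGAP28 at 8.55 and 11.1 against 30.7 to 36.7.

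The 8-cell list, the subject of the study's question, had 47 members, of which 45 are in the count table and 9 had enough counts to test. PNP (16999 counts over all libraries), MFSD2A (8091), CCKBR (5257) and ZNF296 (1686) had the most. All 9 had counts in every group. The filter would also have kept a member with enough counts in the ASO-L1 libraries alone, which none of the 36 untested members reached. With edgeR none of the 9 was called, 1 had an unadjusted p under 0.05, and none was called with DESeq2 (0 at an unadjusted p under 0.05), limma-voom (1) or edgeR without the replicate block (0). The smallest p-values belonged to ZNF296 0.26 ± 0.11 and CCKBR -0.14 ± 0.08 (adjusted p = 0.092 and 0.198). The list as a group did not pass (adjusted p = 0.821; adjusted p = 0.896 with an estimated correlation). Its median log2 fold change was 0.07 and its mean -0.03, so the centre changed sign with the measure. The test leaned upward, and downward without ASO-L1 replicate 1 (adjusted p = 0.935). ZSCAN4, a marker of genome activation, had 1 count in each ASO-L1 library and 0 in the other 4, and TRIM43 had 1 count in ASO-L1 replicate 2. Seen only outside ASO-L1 were HNRNPCL1 (3 counts), TRIM49C (2), ZIM3 (2) and TRIM48 (1). LEUTX, DUXA and DUX4 were among 22 members with 0 counts in every library. A count of 0 allows up to 0.159 CPM in the shallowest library and does not show that a gene is silent. Reads shared between similar genes, such as those of the PRAMEF and MBD3L families, may have been lost in counting, which was not examined here. The 36 untested members summed to 1 and 21 counts in ASO-Ctr, 5 and 14 in sO-L1, and 11 and 16 in ASO-L1, too few for a test.

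Stress genes had the largest median shift of any list. Of 28 tested genes of the integrated stress response and unfolded protein response, 21 were higher, 4 lower and 3 not called (21 and 5 adjusted over the list alone, 16 and 1 without the replicate block). The list rose, with a median log2 fold change of 0.64 (adjusted p = 3.0e-41; adjusted p = 0.414 with an estimated correlation). The leading members were SLC7A11 1.11 ± 0.06, ASNS 0.96 ± 0.05, CHAC1 1.30 ± 0.08 and STC2 1.31 ± 0.06 (adjusted p = 3.1e-21, 8.1e-21, 5.0e-18 and 6.6e-17, or 0.00209, 0.00678, 0.00628 and 0.0012 without the replicate block). SLC7A11 imports cystine, ASNS makes asparagine, CHAC1 degrades glutathione and STC2 is a secreted glycoprotein. The 4 members that fell, HSP90B1, PDIA4, HSPA5 and SDF2L1, are chaperones or chaperone partners of the endoplasmic reticulum. Of 26 p53 targets, 14 were higher, 0 lower and 12 not called (17 and 1 adjusted over the list alone, 9 and 0 without the replicate block), and the list rose with a median of 0.23 (adjusted p = 6.1e-15; adjusted p = 0.414 with an estimated correlation). PHLDA3, an inhibitor of AKT signalling, the cell cycle inhibitor CDKN1A, the RNA-binding factor ZMAT3 and the stress cytokine GDF15 led it: PHLDA3 0.66 ± 0.05, CDKN1A 0.65 ± 0.05, ZMAT3 0.56 ± 0.05 and GDF15 0.97 ± 0.09 (adjusted p = 1.1e-13, 2.0e-13, 8.4e-12 and 1.6e-11, or 0.014, 0.0194, 0.0573 and 0.00805 without the replicate block).

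Of 18 immediate-early genes, 8 were higher, 1 lower and 9 not called (8 and 1 adjusted over the list alone, 2 and 0 without the replicate block). The list rose (adjusted p = 1.6e-04; adjusted p = 0.694 with an estimated correlation). The members with the smallest p were FOSL1 1.14 ± 0.07, CYR61 0.61 ± 0.06, EGR1 -0.58 ± 0.06 and JUN 0.67 ± 0.09 (adjusted p = 9.1e-18, 5.9e-11, 6.1e-11 and 4.0e-08, or 0.00228, 0.0221, 0.142 and 0.0574 without the replicate block), EGR1 being the 1 that fell. Of 24 hypoxia and glycolysis genes, 10 were higher, 3 lower and 11 not called (10 and 3 adjusted over the list alone, 2 and 3 without the replicate block). The list did not pass (adjusted p = 0.185; adjusted p = 0.573 with an estimated correlation). The angiogenic factor VEGFA rose and the mitophagy receptors BNIP3 and BNIP3L fell: VEGFA 0.77 ± 0.06, BNIP3 -0.70 ± 0.07 and BNIP3L -0.55 ± 0.06 (adjusted p = 1.3e-13, 4.3e-11 and 1.4e-10, or 0.00815, 0.00805 and 0.0153 without the replicate block). The hypoxia list was the only one to pass fry here (adjusted p = 0.0424), and the lowest fry value of a camera call was 0.0811, for the stress response list among others. Of 27 interferon-stimulated and RNA-sensing genes, 3 were higher, 5 lower and 19 not called (3 and 5 adjusted over the list alone, 0 and 0 without the replicate block, with 7 at an unadjusted p under 0.05). As a group they did not pass (adjusted p = 0.687; adjusted p = 0.712 with an estimated correlation). IFITM1, a membrane restriction factor, was higher and the helicase DDX60 lower: IFITM1 0.50 ± 0.07 and DDX60 -0.78 ± 0.15 (adjusted p = 9.1e-07 and 9.2e-05, or 0.0757 and 0.0589 without the replicate block).

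Of 22 cholesterol synthesis genes tested, 0 were higher, 16 lower and 6 not called (0 and 18 adjusted over the list alone, 0 and 0 without the replicate block, with 7 at an unadjusted p under 0.05), with a median log2 fold change of -0.22 (adjusted p = 3.7e-11; adjusted p = 0.573 with an estimated correlation). HMGCS1 makes the sterol precursor HMG-CoA and INSIG1 is a sterol sensor: HMGCS1 -0.36 ± 0.05 and INSIG1 -0.37 ± 0.05 (adjusted p = 7.9e-08 and 1.4e-07, or 0.142 and 0.298 without the replicate block). Of 33 genes of DNA replication, 0 were higher, 13 lower and 20 not called (0 and 13 adjusted over the list alone, 0 and 2 without the replicate block), with a median of -0.10 (adjusted p = 2.6e-04; adjusted p = 0.573 with an estimated correlation). GINS2, part of the replicative helicase, and the uracil glycosylase UNG led: GINS2 -0.49 ± 0.05 and UNG -0.44 ± 0.05 (adjusted p = 3.0e-10 and 3.7e-10, or 0.0247 and 0.0177 without the replicate block). Of 30 mitotic genes, 1 was higher, 9 lower and 20 not called (2 and 11 adjusted over the list alone, 0 and 0 without the replicate block, with 3 at an unadjusted p under 0.05). Together they did not pass (adjusted p = 0.059; adjusted p = 0.7 with an estimated correlation). Its smallest p belonged to the spindle gene HMMR and the kinetochore motor CENPE: HMMR -0.31 ± 0.05 and CENPE -0.21 ± 0.05 (adjusted p = 2.1e-06 and 7.9e-04, or 0.0881 and 0.52 without the replicate block). CENPE lost its call without sO-L1 replicate 1 (adjusted p = 0.109). Without ASO-L1 replicate 2 the mitotic list had an adjusted p of 0.00609, with the spread of the lone ASO-L1 library taken from the other groups.

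Pluripotency genes moved both ways. Of 29 core and primed genes, 7 were higher, 8 lower and 14 not called (7 and 9 adjusted over the list alone, 1 and 1 without the replicate block). The group did not pass (adjusted p = 0.941; adjusted p = 0.961 with an estimated correlation). The homeobox factor OTX2 and the growth factor FGF2 rose, and the Nodal antagonist LEFTY1 fell: OTX2 0.49 ± 0.05, FGF2 0.33 ± 0.05 and LEFTY1 -0.92 ± 0.14 (adjusted p = 3.4e-11, 5.4e-07 and 1.8e-06, or 0.154, 0.0493 and 0.0314 without the replicate block). Of 12 naive pluripotency genes, 3 were higher, 1 lower and 8 not called (3 and 1 adjusted over the list alone, 1 and 0 without the replicate block). Tested as a list they did not pass (adjusted p = 0.32; adjusted p = 0.7 with an estimated correlation). KLF4 and DPPA3, a maternal factor, rose and NANOG fell: KLF4 1.86 ± 0.17, DPPA3 0.97 ± 0.20 and NANOG -0.17 ± 0.05 (adjusted p = 4.3e-12, 1.7e-04 and 0.0128, or 0.00815, 0.0661 and 0.29 without the replicate block). NANOG lost its call with DESeq2 (adjusted p = 0.0613), and when sO-L1 replicate 1 or ASO-L1 replicate 1 was left out.

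The title of the series names PRC2 and the nucleolus. Of 13 PRC2 subunits and cofactors, 4 were higher, 1 lower and 8 not called (4 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 4 at an unadjusted p under 0.05). This list did not pass (adjusted p = 0.059; adjusted p = 0.573 with an estimated correlation). The cofactors PHF1 and JARID2 were higher: PHF1 0.43 ± 0.06 and JARID2 0.22 ± 0.05 (adjusted p = 2.1e-07 and 4.0e-04, or 0.0517 and 0.243 without the replicate block). JARID2 lost its call without sO-L1 replicate 1 (adjusted p = 0.0939). The 39 homeobox cluster genes are in the table, but none had enough counts to test. Of 49 nucleolar and rRNA synthesis genes, 7 were higher, 1 lower and 41 not called (6 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 5 at an unadjusted p under 0.05). Jointly they did not pass (adjusted p = 0.0894; adjusted p = 0.573 with an estimated correlation), with RRP12 and the polymerase subunit POLR1A first: RRP12 0.31 ± 0.05 and POLR1A 0.24 ± 0.05 (adjusted p = 2.9e-06 and 1.6e-04, or 0.0982 and 0.151 without the replicate block). POLR1A lost its call without sO-L1 replicate 1 (adjusted p = 0.0714). Without sO-L1 replicate 1 the PRC2 and nucleolar lists passed upward (adjusted p = 0.0266 and 0.0386), as they did without ASO-L1 replicate 1 (adjusted p = 0.0142 and 0.0366). Of 79 cytosolic ribosomal protein genes, 15 were higher, 4 lower and 60 not called (17 and 4 adjusted over the list alone, 0 and 0 without the replicate block, with 0 at an unadjusted p under 0.05). That list rose by a median of 0.07 (adjusted p = 0.00184; adjusted p = 0.7 with an estimated correlation), and lost its call without the replicate block (adjusted p = 0.11) and without sO-L1 replicate 2 (adjusted p = 0.191). RPL39 rose and RPL12, against the list, fell: RPL39 0.23 ± 0.05 and RPL12 -0.19 ± 0.05 (adjusted p = 2.2e-04 and 0.00138, or 0.381 and 0.351 without the replicate block). RPL12 lost its call without ASO-L1 replicate 1 (adjusted p = 0.0782). Many ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. Of 23 L1 silencing factors, 3 were higher, 5 lower and 15 not called (3 and 8 adjusted over the list alone, 0 and 1 without the replicate block). As a group they did not pass (adjusted p = 0.505; adjusted p = 0.712 with an estimated correlation). SAMHD1, a dNTPase that restricts L1, fell and the scaffold factor SAFB2 rose: SAMHD1 -0.71 ± 0.06 and SAFB2 0.23 ± 0.05 (adjusted p = 1.5e-13 and 2.2e-04, or 0.00702 and 0.126 without the replicate block).

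Markers of other cell types were mostly not called. Of 15 fibroblast and mesenchyme markers, 3 were higher, 1 lower and 11 not called (3 and 1 adjusted over the list alone, 1 and 0 without the replicate block). The list passed upward in camera (adjusted p = 0.00847; adjusted p = 0.573 with an estimated correlation) on a mean of 0.13 while its median was -0.02, and it lost the call without the replicate block (adjusted p = 0.225). The call was also lost with no filter on low counts (adjusted p = 0.685), with limma-voom (adjusted p = 0.0893) and after thinning (adjusted p = 0.157), and was kept in 10 of 16 alternatives. The intermediate filament gene VIM, which stem cells also express, and the collagen gene COL1A1 rose: VIM 0.98 ± 0.05 and COL1A1 0.63 ± 0.06 (adjusted p = 1.0e-21 and 3.3e-09, or 0.067 and 0.029 without the replicate block). Of 19 neuroectoderm markers, 2 were higher, 1 lower and 16 not called (1 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 2 at an unadjusted p under 0.05). Of 12 mesoderm markers, 3 were higher, 0 lower and 9 not called (3 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 3 at an unadjusted p under 0.05). Among 12 endoderm markers, 0 were higher, 1 lower and 11 not called (0 and 1 adjusted over the list alone, 0 and 1 without the replicate block), the 1 being the pioneer factor FOXA2: FOXA2 -1.13 ± 0.16 (adjusted p = 3.0e-07, or 0.0213 without the replicate block). Among 11 trophoblast and amnion markers, 1 was higher, 0 lower and 10 not called (0 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 0 at an unadjusted p under 0.05), the 1 being TFAP2C: TFAP2C 0.69 ± 0.25 (adjusted p = 0.036, or 0.439 without the replicate block). TFAP2C lost its call without sO-L1 replicate 1 (adjusted p = 0.49), sO-L1 replicate 2 (adjusted p = 0.0509), ASO-L1 replicate 1 (adjusted p = 0.444) and ASO-L1 replicate 2 (adjusted p = 0.0593). None of these 4 lists passed (adjusted p = 0.505 for the neuroectoderm, 0.687 for the mesoderm, 0.326 for the endoderm and 0.56 for the trophoblast).

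Among RNA classes that reflect library quality, 33 replication-dependent histone genes and 15 mitochondrially encoded genes did not pass as lists (adjusted p = 0.185 and 0.698). Of the histone genes, 1 was higher, 0 lower and 32 not called (0 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 2 at an unadjusted p under 0.05). Of the mitochondrial genes, 2 were higher, 1 lower and 12 not called (2 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 2 at an unadjusted p under 0.05). MT-ND1, a subunit of respiratory complex I, rose: MT-ND1 0.30 ± 0.05 (adjusted p = 2.5e-06, or 0.0912 without the replicate block). The histone gene that passed was HIST1H1E: HIST1H1E 0.81 ± 0.27 (adjusted p = 0.0261, or 0.198 without the replicate block). HIST1H1E lost its call without sO-L1 replicate 1 (adjusted p = 0.0952), sO-L1 replicate 2 (adjusted p = 0.323), ASO-L1 replicate 1 (adjusted p = 0.0768) and ASO-L1 replicate 2 (adjusted p = 0.302). The histone list passed without sO-L1 replicate 1 (adjusted p = 0.0266) and without ASO-L1 replicate 1 (adjusted p = 0.0366). The median, mean and test differed in sign for the mitochondrial list (median -0.01, mean 0.03, test upward) and the mesoderm list (median -0.04, mean 0.07, test upward).

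**Figure D2:**
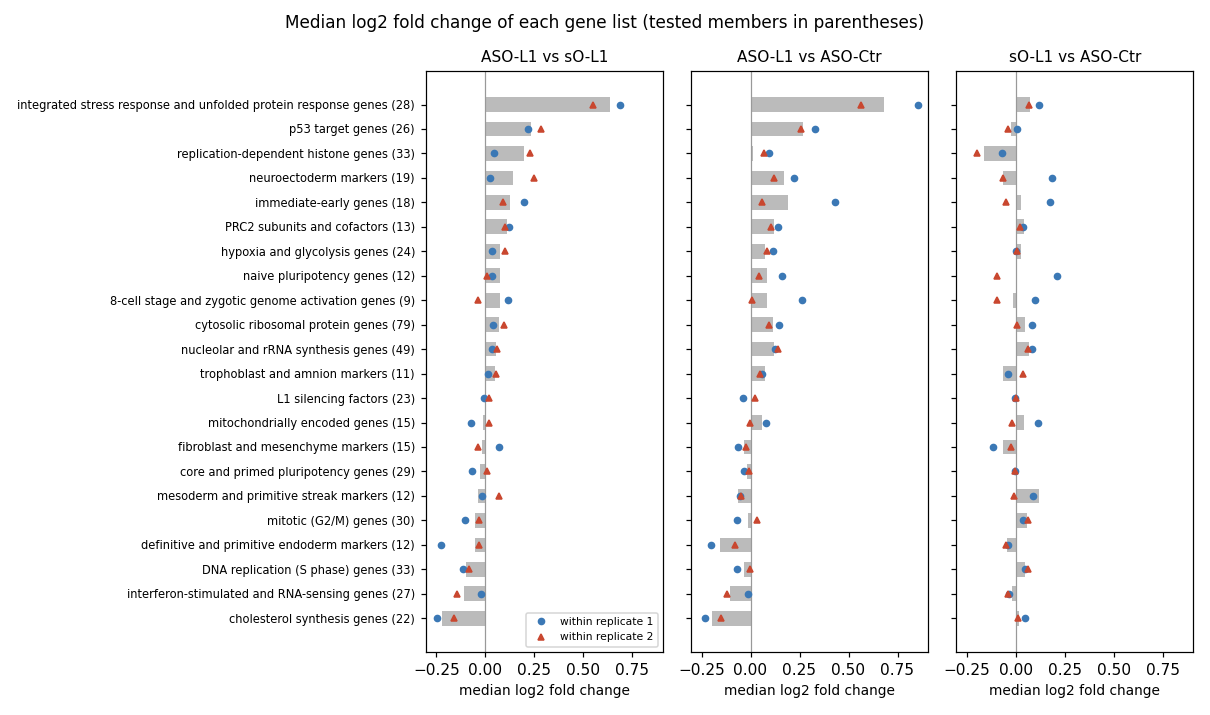
Median log2 fold change (horizontal axis) of each gene list, with tested members in parentheses, in the 3 comparisons. Bars are the fitted medians, circles and triangles the medians within replicates 1 and 2. The integrated stress response list has the longest bars in both ASO-L1 panels, at 0.64 and 0.68, against 0.07 in sO-L1 vs ASO-Ctr.

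ASO-L1 against ASO-Ctr compares the L1 antisense oligo with the non-targeting antisense oligo. The integrated stress response and p53 lists were higher in ASO-L1, the cholesterol synthesis list was lower, and the nucleolar and ribosomal protein lists were slightly higher, by camera at its preset correlation. All 5 calls were lost (adjusted p = 0.265, 0.265, 0.587, 0.472 and 0.614 with an estimated correlation). Without the replicate block 1 of 22 cholesterol, 0 of 49 nucleolar and 0 of 79 ribosomal protein genes were called. By the same camera test the nucleolar list also rose in sO-L1 against ASO-Ctr (adjusted p = 6.7e-07). It did not pass in ASO-L1 against sO-L1 (adjusted p = 0.0894), so its shift is not particular to ASO-L1. The ribosomal protein list passed upward in both of these comparisons (adjusted p = 0.00178 and 0.00184). ASNS, the asparagine synthetase, rose 2.21-fold, from 102 ± 6.39 to 227 ± 33.7 CPM (mean ± SD, n = 2). KLF4 rose 3.76-fold, from 1.22 ± 0.454 to 5.34 ± 0.951 CPM. LEFTY1 fell from 6.39 ± 0.796 to 2.41 ± 0.0873 CPM.

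Among the largest increases were ANXA1 3.34 ± 0.22, TAC1 2.17 ± 0.19, ATF5 2.01 ± 0.07, VGF 1.97 ± 0.07, KLF4 1.91 ± 0.18, INHBE 1.90 ± 0.10 and ARHGAP9 1.85 ± 0.21, with adjusted p-values from 4.9e-28 for ATF5 to 1.9e-09 for ARHGAP9. VGF encodes a neuropeptide precursor. Of these, ANXA1 lost its call without the replicate block (adjusted p = 0.0588), and the other 6 listed passed in that fit. The largest decreases were FAM189A1 -2.27 ± 0.14, ARHGAP28 -1.85 ± 0.08, IMMP2L -1.62 ± 0.19, TBX10 -1.45 ± 0.16, SAMD12 -1.44 ± 0.12, TMEM179 -1.39 ± 0.15, LEFTY1 -1.38 ± 0.14 and RP11-526J3.3 -1.28 ± 0.14, with adjusted p-values from 1.6e-24 for ARHGAP28 to 2.3e-09 for IMMP2L. All 8 passed without the replicate block as well (adjusted p = 5.6e-04 for ARHGAP28 to 0.0234 for RP11-526J3.3). The median genomic span was 70.4 kb for genes lower, 22.4 kb for genes higher and 27.3 kb for genes not called.

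In this comparison edgeR called 1893 genes higher and 2227 lower of 19156, with a median absolute log2 fold change of 0.29. Without the replicate block the counts were 173 and 201, with 3207 genes at an unadjusted p under 0.05, and 372 of these 374 genes were also called with it. The counts were 1097 and 1313 without ASO-Ctr replicate 1 and 1071 and 1313 without ASO-L1 replicate 1. A change of at least 2-fold was seen for 105 of the genes higher and 105 of the genes lower.

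None of the 9 tested 8-cell members was called by edgeR, with 3 at an unadjusted p under 0.05, nor by DESeq2 (0), limma-voom (2) or edgeR without the replicate block (0). MFSD2A, a lipid transporter, and PNP, a purine phosphorylase, had the smallest p: MFSD2A -0.18 ± 0.07 and PNP 0.13 ± 0.05 (adjusted p = 0.0565 and 0.0959). After thinning to the shallowest library MFSD2A was called, lower (adjusted p = 0.0433). Without ASO-L1 replicate 2, MFSD2A and ALPPL2, a placental-type phosphatase and also a naive marker, had adjusted p = 0.0081 and 0.0481 (0.158 for ALPPL2 with all libraries), but ASO-L1 then had 1 library, with its spread taken from the other groups. The list did not pass (adjusted p = 0.794; adjusted p = 0.901 with an estimated correlation), with a median of 0.09 and a mean of -0.02. Its test leaned upward, and downward without ASO-Ctr replicate 1 (adjusted p = 0.954).

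Of 28 genes of the integrated stress response and unfolded protein response, 21 were higher, 3 lower and 4 not called (22 and 3 adjusted over the list alone, 19 and 0 without the replicate block), with a median log2 fold change of 0.68 (adjusted p = 6.4e-55; adjusted p = 0.265 with an estimated correlation). They were led by ASNS, SLC7A11, CHAC1 and MTHFD2, a mitochondrial folate enzyme: ASNS 1.15 ± 0.05, SLC7A11 1.12 ± 0.06, CHAC1 1.55 ± 0.08 and MTHFD2 0.83 ± 0.05 (adjusted p = 1.4e-23, 8.3e-21, 5.9e-20 and 4.8e-18, or 0.00261, 0.00189, 0.00237 and 0.00413 without the replicate block). PDIA4, HSP90B1 and HSPA5, chaperones of the endoplasmic reticulum, fell. Of 26 p53 targets, 15 were higher, 1 lower and 10 not called (17 and 1 adjusted over the list alone, 8 and 0 without the replicate block), with a median of 0.27 (adjusted p = 2.6e-12; adjusted p = 0.265 with an estimated correlation). The fry test passed for the stress response (adjusted p = 0.0433), p53 (adjusted p = 0.0208) and nucleolar lists (adjusted p = 0.0369), and for the hypoxia list (adjusted p = 0.0208). PHLDA3, the growth arrest gene GADD45A and MDM2, which degrades p53, led: PHLDA3 0.71 ± 0.06, GADD45A 0.75 ± 0.07 and MDM2 0.48 ± 0.05 (adjusted p = 2.8e-14, 3.7e-12 and 1.4e-10, or 0.0111, 0.0228 and 0.0159 without the replicate block). Of 18 immediate-early genes, 9 were higher, 1 lower and 8 not called (9 and 1 adjusted over the list alone, 3 and 0 without the replicate block). The list rose (adjusted p = 6.9e-06; adjusted p = 0.614 with an estimated correlation), with the AP-1 member FOSL1 first: FOSL1 0.85 ± 0.07, CYR61 0.71 ± 0.06 and CTGF 0.56 ± 0.06 (adjusted p = 1.9e-13, 1.8e-12 and 2.2e-10, or 0.00693, 0.0133 and 0.0305 without the replicate block). Of 22 cholesterol synthesis genes, 0 were higher, 16 lower and 6 not called (0 and 18 adjusted over the list alone, 0 and 1 without the replicate block), and the list fell, with a median of -0.20 (adjusted p = 1.9e-08; adjusted p = 0.587 with an estimated correlation), with the reductase DHCR7 and INSIG1 among those lower: DHCR7 -0.28 ± 0.05 and INSIG1 -0.29 ± 0.05 (adjusted p = 1.2e-05 and 2.1e-05, or 0.148 and 0.431 without the replicate block).

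Of 49 nucleolar and rRNA synthesis genes, 23 were higher, 1 lower and 25 not called (25 and 2 adjusted over the list alone, 0 and 0 without the replicate block, with 15 at an unadjusted p under 0.05), with a median of 0.12 (adjusted p = 2.4e-06; adjusted p = 0.472 with an estimated correlation). The processing factors RRP12 and RRP1 and the snoRNP protein NOP58 led: RRP12 0.34 ± 0.05, RRP1 0.34 ± 0.05 and NOP58 0.25 ± 0.05 (adjusted p = 8.3e-07, 1.9e-06 and 5.3e-05, or 0.0771, 0.089 and 0.173 without the replicate block). Of 79 ribosomal protein genes, 34 were higher, 2 lower and 43 not called (47 and 3 adjusted over the list alone, 0 and 0 without the replicate block, with 1 at an unadjusted p under 0.05), with a median of 0.11 (adjusted p = 3.3e-07; adjusted p = 0.614 with an estimated correlation). RPL8 rose and RPL12 fell: RPL8 0.24 ± 0.05 and RPL12 -0.21 ± 0.05 (adjusted p = 1.1e-04 and 5.4e-04, or 0.245 and 0.306 without the replicate block). Of 13 PRC2 subunits and cofactors, 4 were higher, 0 lower and 9 not called (6 and 0 adjusted over the list alone, 1 and 0 without the replicate block), and the list rose by a median of 0.12 (adjusted p = 0.0231; adjusted p = 0.587 with an estimated correlation). It lost that call without ASO-Ctr replicate 2 (adjusted p = 0.0865) and without ASO-L1 replicate 2 (adjusted p = 0.139). PHF1, AEBP2 and the core subunit EED were higher: PHF1 0.48 ± 0.06, AEBP2 0.23 ± 0.05 and EED 0.23 ± 0.06 (adjusted p = 2.5e-08, 8.7e-04 and 0.00176, or 0.0319, 0.176 and 0.249 without the replicate block). EED lost its call without ASO-Ctr replicate 1 (adjusted p = 0.0541) and ASO-L1 replicate 2 (adjusted p = 0.0539).

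Pluripotency, cell cycle and the remaining stress lists did not pass (adjusted p = 0.928 for the core and primed genes, 0.421 for the naive genes, 0.188 for the replication genes, 0.794 for the mitotic genes, 0.133 for the hypoxia genes, 0.525 for the interferon genes and 0.525 for the L1 silencing factors). Of 29 core and primed genes, 6 were higher, 7 lower and 16 not called (7 and 8 adjusted over the list alone, 1 and 2 without the replicate block), among them OTX2 and LEFTY1: OTX2 0.50 ± 0.05 and LEFTY1 -1.38 ± 0.14 (adjusted p = 3.2e-11 and 8.4e-11, or 0.143 and 0.00825 without the replicate block). Of 12 naive genes, 2 were higher, 1 lower and 9 not called (2 and 1 adjusted over the list alone, 1 and 0 without the replicate block): KLF4 1.91 ± 0.18 and NANOG -0.22 ± 0.05 (adjusted p = 9.2e-12 and 0.00116, or 0.00716 and 0.176 without the replicate block). NANOG lost its call without ASO-L1 replicate 1 (adjusted p = 0.0916). Of 33 replication genes, 1 was higher, 6 lower and 26 not called (1 and 6 adjusted over the list alone, 0 and 1 without the replicate block), with UNG first: UNG -0.34 ± 0.05 and GINS2 -0.39 ± 0.05 (adjusted p = 1.9e-07 and 2.0e-07, or 0.0378 and 0.0551 without the replicate block). Of 30 mitotic genes, 1 was higher, 5 lower and 24 not called (1 and 3 adjusted over the list alone, 0 and 0 without the replicate block, with 0 at an unadjusted p under 0.05). Of 24 hypoxia genes, 10 were higher, 3 lower and 11 not called (10 and 3 adjusted over the list alone, 2 and 3 without the replicate block): VEGFA 0.90 ± 0.07 and BNIP3 -0.66 ± 0.07 (adjusted p = 4.1e-15 and 6.8e-10, or 0.00473 and 0.0119 without the replicate block). Of 27 interferon genes, 3 were higher, 6 lower and 18 not called (3 and 6 adjusted over the list alone, 0 and 1 without the replicate block), the ISG15 protease USP18 having the smallest p: USP18 -0.80 ± 0.14 (adjusted p = 2.0e-05, or 0.0356 without the replicate block). Of 23 L1 silencing factors, 3 were higher, 4 lower and 16 not called (4 and 4 adjusted over the list alone, 0 and 1 without the replicate block): SAMHD1 -0.73 ± 0.06 and CBX5 -0.30 ± 0.05 (adjusted p = 1.0e-13 and 3.8e-06, or 0.00563 and 0.108 without the replicate block). The L1 silencing list had a median of 0.01, a mean of -0.08 and a test that was downward.

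Among markers of other cell types no list passed (adjusted p = 0.205 for the fibroblast, 0.525 for the neuroectoderm, 0.794 for the mesoderm, 0.273 for the endoderm and 0.679 for the trophoblast). Of 15 fibroblast markers, 3 were higher, 2 lower and 10 not called (3 and 3 adjusted over the list alone, 1 and 0 without the replicate block), VIM and COL1A1 again being higher: VIM 0.91 ± 0.05 and COL1A1 0.61 ± 0.07 (adjusted p = 2.1e-20 and 1.2e-08, or 0.0853 and 0.032 without the replicate block). Of 19 neuroectoderm markers, 2 were higher, 2 lower and 15 not called (3 and 2 adjusted over the list alone, 0 and 0 without the replicate block, with 2 at an unadjusted p under 0.05). Of 12 mesoderm markers, 2 were higher, 1 lower and 9 not called (2 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 4 at an unadjusted p under 0.05). Of 11 trophoblast markers, 1 was higher, 1 lower and 9 not called (2 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 1 at an unadjusted p under 0.05). Of 12 endoderm markers, 0 were higher, 2 lower and 10 not called (0 and 2 adjusted over the list alone, 0 and 1 without the replicate block), with FOXA2 lower: FOXA2 -0.93 ± 0.17 (adjusted p = 3.2e-05, or 0.0428 without the replicate block). The histone list (adjusted p = 0.928) and the mitochondrial list (adjusted p = 0.273) did not pass either. The mitochondrial list passed without ASO-Ctr replicate 2 (adjusted p = 0.0315). Of 33 histone genes, 0 were higher, 3 lower and 30 not called (0 and 2 adjusted over the list alone, 0 and 0 without the replicate block, with 1 at an unadjusted p under 0.05). Of 15 mitochondrial genes, 4 were higher, 1 lower and 10 not called (4 and 1 adjusted over the list alone, 0 and 0 without the replicate block, with 3 at an unadjusted p under 0.05). The median and mean had opposite signs for the fibroblast (-0.04 and 0.08, test upward), mesoderm (-0.06 and 0.19, upward) and trophoblast lists (0.08 and -0.04, upward).

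Most genes called in one ASO-L1 comparison moved the same way in the other. TAC1, ATF5, KLF4 and INHBE were among the largest increases and FAM189A1, ARHGAP28, IMMP2L, TBX10 and TMEM179 among the largest decreases in both. In all, 1208 genes were higher and 1575 lower in both, and 6 were called in opposite directions. Independent lists of the same sizes would share 195.9 and 282.5 genes, but both comparisons use the same ASO-L1 libraries. In 20 simulations of unchanged groups that share these libraries the mean overlap was 0.35 genes higher and 0.3 lower. At most 4 genes were called in ASO-L1 against sO-L1, the only comparison whose calls were counted. These simulations thus do not show how much overlap sharing brings among changed genes. Without the replicate block 126 genes were higher and 118 lower in both, and without ASO-L1 replicate 1 the counts were 606 and 783. Without sO-L1 replicate 1 they were 704 and 985, and without sO-L1 replicate 2 the count lower was 1003. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.695 and a covariance of 0.0965, against 0.469 and 0.0285 in those simulations.

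The sense L1 oligo against the non-targeting oligo (sO-L1 against ASO-Ctr) gives the difference between the control oligos. HMCN1, an extracellular matrix protein, was lower in sO-L1, at 10.3 ± 4.13 against 20.8 ± 4.36 CPM (mean ± SD, n = 2), and ARRDC3, an arrestin family member, was higher, at 23.2 ± 1.96 against 16.1 ± 2.46 CPM. The largest increases were ZNF441 0.75 ± 0.18, SYT4 0.67 ± 0.16, ARRDC3 0.54 ± 0.08 and NMU 0.54 ± 0.15 (adjusted p = 0.0157, 0.0156, 2.4e-05 and 0.0409). SYT4 is a synaptotagmin and NMU a neuropeptide. The largest decreases were RPL37P2 -1.38 ± 0.23, HMCN1 -0.99 ± 0.09, ABCB1 -0.74 ± 0.19 and ONECUT2 -0.72 ± 0.17 (adjusted p = 0.00125, 2.5e-10, 0.0283 and 0.0145). RPL37P2 is a pseudogene that shares sequence with its parent gene, so its value is uncertain, and ABCB1 is a drug efflux pump. None of these 8 passed without the replicate block. With limma-voom and all libraries kept, ZNF441, SYT4, NMU, ABCB1 and ONECUT2 also lost their calls (adjusted p = 0.05635, 0.082, 0.1155, 0.105 and 0.0655).

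In this comparison 126 genes were higher and 204 lower, with a median absolute log2 fold change of 0.25. The median genomic span was 135 kb for genes lower, 23.5 kb for genes higher and 29.3 kb for genes not called. The rank correlation of fold change with span was -0.168 within replicate 1 and -0.0357 within replicate 2. ASO-Ctr replicate 1, the shallowest library, lay apart from the others on the first principal component (-45.7, the others from -9.541 to 25.15). Without the replicate block edgeR called 0 higher and 0 lower, with 569 genes at an unadjusted p under 0.05, whereas DESeq2 with the block called 54 and 71 and limma-voom 62 and 106. The number of calls depended on the library left out: 16 genes without sO-L1 replicate 1 (3 higher and 13 lower), 89 without ASO-Ctr replicate 1 (18 and 71), 353 without sO-L1 replicate 2 and 346 without ASO-Ctr replicate 2, each with 1 library in that group and its spread taken from the others. The counts higher were 211 without ASO-L1 replicate 1 and 212 without ASO-L1 replicate 2. ZNF441 lost its call without ASO-Ctr replicate 2 (adjusted p = 0.313), sO-L1 replicate 1 (adjusted p = 0.16) and sO-L1 replicate 2 (adjusted p = 0.298). SYT4 lost its call without ASO-Ctr replicate 1 (adjusted p = 0.0818), ASO-Ctr replicate 2 (adjusted p = 0.0786), sO-L1 replicate 1 (adjusted p = 0.16) and sO-L1 replicate 2 (adjusted p = 0.291). NMU lost its call without ASO-Ctr replicate 1 (adjusted p = 0.0617), ASO-Ctr replicate 2 (adjusted p = 0.488), sO-L1 replicate 1 (adjusted p = 0.396) and sO-L1 replicate 2 (adjusted p = 0.374). ABCB1 lost its call without ASO-Ctr replicate 1 (adjusted p = 0.113), ASO-Ctr replicate 2 (adjusted p = 0.206), sO-L1 replicate 1 (adjusted p = 0.433) and sO-L1 replicate 2 (adjusted p = 0.214). ONECUT2 lost its call without ASO-Ctr replicate 2 (adjusted p = 0.315), sO-L1 replicate 1 (adjusted p = 0.559) and sO-L1 replicate 2 (adjusted p = 0.0577). RPL37P2 lost its call without ASO-Ctr replicate 1 (adjusted p = 0.158) and sO-L1 replicate 1 (adjusted p = 0.232).

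Some lists passed by small shifts. Of 49 nucleolar and rRNA synthesis genes, 4 were higher, 0 lower and 45 not called (8 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 3 at an unadjusted p under 0.05), with a median of 0.07 (adjusted p = 6.7e-07; adjusted p = 0.808 with an estimated correlation). Of 28 genes of the integrated stress response, 2 were higher, 0 lower and 26 not called (5 and 0 adjusted over the list alone, 0 and 0 without the replicate block, with 2 at an unadjusted p under 0.05), with a median of 0.07 (adjusted p = 3.9e-05; adjusted p = 0.969 with an estimated correlation), a call lost without ASO-Ctr replicate 1 (adjusted p = 0.287). None of the 79 ribosomal protein genes was called by edgeR, with 9 at an unadjusted p under 0.05, nor by DESeq2 (8) or limma-voom (12), yet the list passed upward (adjusted p = 0.00178; adjusted p = 0.976 with an estimated correlation). It lost that call without the replicate block (adjusted p = 0.0721), without ASO-Ctr replicate 1 (adjusted p = 0.537) and without sO-L1 replicate 1 (adjusted p = 0.848). The replication genes (adjusted p = 3.3e-04; adjusted p = 0.969 with an estimated correlation) and the mitotic genes (adjusted p = 0.00305; adjusted p = 0.976 with an estimated correlation) passed upward with 1 and 0 members called, of 6 and 9 at an unadjusted p under 0.05. Both lost the call without ASO-Ctr replicate 2 (adjusted p = 0.106 and 0.665). The histone list passed downward with 2 of 33 members called (adjusted p = 0.0253; adjusted p = 0.969 with an estimated correlation), and lost that call without ASO-Ctr replicate 2 (adjusted p = 0.342) and without sO-L1 replicate 2 (adjusted p = 0.782).

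The other lists did not pass in sO-L1 against ASO-Ctr. With 1 library left in a group, and its spread taken from the others, some of these passed. Without ASO-Ctr replicate 2 the immediate-early (adjusted p = 6.8e-04) and mitochondrial lists (adjusted p = 0.0123) passed. Without sO-L1 replicate 2 the cholesterol (adjusted p = 0.0159) and mitochondrial lists (adjusted p = 0.00862) passed. With both compared groups whole, the fibroblast list passed without ASO-L1 replicate 1 (adjusted p = 0.0492) and without ASO-L1 replicate 2 (adjusted p = 0.0486). The counts higher and lower were 0 and 1 for the p53 targets, 1 and 0 for the cholesterol genes, 0 and 1 for the immediate-early genes, 1 and 0 for the interferon genes, 0 and 1 for the mitochondrial genes, 1 and 1 for the L1 silencing factors, 2 and 0 for the core and primed genes, 0 and 1 for the fibroblast markers and 0 and 1 for the mesoderm markers. In edgeR no member of the hypoxia, PRC2, naive, neuroectoderm, endoderm and trophoblast lists was called, with 0, 3, 1, 2, 1 and 2 at an unadjusted p under 0.05, and none was called by DESeq2, limma-voom or edgeR without the block. Among the 9 tested 8-cell genes none was called by edgeR, DESeq2, limma-voom or edgeR without the block, with 0 at an unadjusted p under 0.05 in each (adjusted p = 0.976 for the list). The median and the test differed in sign for the 8-cell (-0.01, upward), naive (0.00168, downward), core (0.00438, downward), L1 silencing (0.00584, downward), neuroectoderm (-0.06, upward) and mesoderm lists (0.12, downward).

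The authors' deposited table of ASO-L1 against sO-L1 lists 16753 genes, of which 3882 have an adjusted p under 0.05, 1882 higher and 2000 lower. Of these, 3781 were also called here in the same direction and 101 were not called, with 0 in the opposite direction. Across the genes in both, Spearman's rank correlation of the log2 fold changes was 0.999. For ATF5 and ARHGAP28 the authors' deposited table gives log2 fold changes of 1.93 and -1.65.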

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

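Thinning was chosen after the results were seen, and the other alternatives before. With 2 libraries per group the calls depend on the replicate block, whose pairing is not established, and the shallowest library limits genes with few counts. DESeq2 gave no adjusted p (NA) for 5942, 5571 and 12999 genes in the 3 comparisons. In the 16 alternatives run for lists and 15 for named genes, none changed sign with an adjusted p under 0.05 in either fit, of 57 that changed sign. The cause was not tested for any of these changes.

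Genes higher and lower were 175 and 177 (ASO-L1 vs sO-L1), 173 and 201 (ASO-L1 vs ASO-Ctr), 0 and 0 (sO-L1 vs ASO-Ctr) and 126 and 118 (both ASO-L1 comparisons) with no replicate block. With DESeq2 they were 1052 and 1312, 1151 and 1290, 54 and 71, and 723 and 882. At a fold of at least 2 they were 160 and 64, 105 and 105, 1 and 10, and 70 and 30. In sO-L1 vs ASO-Ctr they were 62 and 106 with limma-voom, 206 were higher with the 4 libraries alone, and 226 at adjusted p under 0.1. With a library left out, its group's lone library being assumed to vary like the others, they ranged from 841 to 2130 and 1110 to 2546, 1071 to 1909 and 1313 to 2178, 3 to 212 and 13 to 283, and 606 to 1044 and 783 to 1368. The 8-cell list stayed above 0.05, at 0.642 to 0.995 and 0.447 to 0.954, but changed direction, from upward to downward, in ASO-L1 vs sO-L1 without ASO-L1 replicate 1 (0.935) and in ASO-L1 vs ASO-Ctr without ASO-Ctr replicate 1 (0.954).

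Lists changed sign at these camera adjusted p-values (fry's own for fry). With DESeq2 size factors: neuroectoderm 0.9927 (sO-L1 vs ASO-Ctr). Under upper-quartile scaling: core 0.982 (ASO-L1 vs sO-L1). With no low-count filter: mitotic 0.9626, mesoderm 0.9052, fibroblast 0.9626 (ASO-L1 vs ASO-Ctr), 8-cell 0.9706, L1 silencing 0.9308, trophoblast 0.9706 (sO-L1 vs ASO-Ctr). Under the CPM filter: core 0.9383 (ASO-L1 vs sO-L1), histone 0.7268 (ASO-L1 vs ASO-Ctr), endoderm 0.8628 (sO-L1 vs ASO-Ctr). With limma-voom: 8-cell 0.993, L1 silencing 0.993, neuroectoderm 0.993 (sO-L1 vs ASO-Ctr). Under no replicate block: naive 0.9413, neuroectoderm 0.9658, mesoderm 0.9526 (sO-L1 vs ASO-Ctr). With fry: histone 0.9745 (ASO-L1 vs ASO-Ctr), neuroectoderm 0.9877 (sO-L1 vs ASO-Ctr). Under thinning: core 0.9934 (ASO-L1 vs sO-L1), core 0.967 (ASO-L1 vs ASO-Ctr), 8-cell 0.9417, naive 0.9417, trophoblast 0.9417 (sO-L1 vs ASO-Ctr). Over all left-out libraries, the adjusted p of lists that changed sign without one of them ranged as follows. ASO-L1 vs sO-L1: 8-cell 0.642 to 0.995, core 0.66 to 0.948, interferon 0.384 to 0.945, mitochondrial 0.18 to 0.715. ASO-L1 vs ASO-Ctr: 8-cell 0.447 to 0.954, core 0.67 to 0.977, mitotic 0.202 to 0.821, histone 0.581 to 0.955. sO-L1 vs ASO-Ctr: 8-cell 0.546 to 0.997, L1 silencing 0.447 to 0.997, cholesterol 0.0159 to 0.934, core 0.749 to 0.997, endoderm 0.764 to 0.977, immediate-early 6.8e-04 to 0.848, interferon 0.287 to 0.934, mesoderm 0.537 to 0.997, mitochondrial 0.00862 to 0.946, naive 0.328 to 0.997, neuroectoderm 0.568 to 0.997, p53 0.0891 to 0.893, trophoblast 0.807 to 0.997. The log2 fold change ranged over HIST1H1C ASO-L1 vs sO-L1 -0.0018 to 0.41 and KRT8 ASO-L1 vs sO-L1 -0.012 to 0.11. Other settings of scaling, filter, tool and depth gave calls to further lists: PRC2 0.0311 (no low-count filter), nucleolar 0.00447 (no low-count filter), mitotic 0.0217 (no low-count filter), histone 0.0143 (no low-count filter), PRC2 0.0364 (limma-voom), nucleolar 0.0364 (limma-voom), mitotic 0.0364 (limma-voom) and mitotic 0.0461 (thinning) in ASO-L1 vs sO-L1, hypoxia 0.0488 (no low-count filter) in ASO-L1 vs ASO-Ctr and fibroblast 0.0481 (limma-voom) and fibroblast 0.0488 (4 libraries of the 2 groups only) in sO-L1 vs ASO-Ctr. Calls lost there were fibroblast 0.685 (no low-count filter), fibroblast 0.0893 (limma-voom) and fibroblast 0.157 (thinning) in ASO-L1 vs sO-L1 and histone 0.167 (thinning) in sO-L1 vs ASO-Ctr.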

Other observations

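The biotype groups, the regression, the tests within GC bins and the test of an equal effect of any L1 oligo were chosen after the results were seen. In ASO-L1 against sO-L1, of 156 long intergenic RNAs 20 were higher and 7 lower, and of 263 antisense RNAs 20 were higher and 4 lower, beside 1585 and 2236 of 14064 protein-coding genes. Most of each class was not called, and no test compared the classes. Against ASO-Ctr the counts were 17 and 11, and 17 and 7. Of 367 processed pseudogenes, 9 were higher and 4 lower, and 4 and 8 against ASO-Ctr. The strand setting of the counting is not stated, so antisense RNAs are uncertain.

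Among protein-coding genes of the longest decile (median span 294 kb), 30.2% were lower in ASO-L1 against sO-L1, 37.1% in ASO-L1 against ASO-Ctr and 4.48% in sO-L1 against ASO-Ctr. Of all protein-coding genes, 15.9%, 14.4% and 1.16% were lower. The control oligos differ on few calls, none of which passed without the replicate block. Their fold changes had a rank correlation of -0.181 with transcript length and -0.118 with span, so the pattern there is not shown to be the same. Transcript length is excluded as the whole cause in ASO-L1 against sO-L1 (-0.173 at its weakest tertile), the only comparison in which this was tested. Fold changes hardly followed it there (-0.0141), and did so more in ASO-L1 against ASO-Ctr (-0.1055). In both ASO-L1 comparisons 1 deviating library is excluded as the whole cause (-0.126 at the weakest of 4 differences). An equal effect of any L1 oligo cannot be the whole cause, since it would cancel in ASO-L1 against sO-L1. There the rank correlation with span was -0.126 at its weakest, which is the pattern itself and not a separate test. Unequal effects of the L1 oligos are not covered by it. By the limit of 0.5 set before, an effect of any L1 oligo on part of the pattern fits. The correlation with span in sO-L1 against ASO-Ctr was 0.58 of that in ASO-L1 against ASO-Ctr. Both use the same ASO-Ctr libraries, so a span trend in these alone would also give a positive ratio. The ratio was 0.741 in replicate 1, which holds the outlying ASO-Ctr library, and 0.237 in replicate 2. A regression with transcript length, GC content and expression gave span terms of 0.0024 in sO-L1 against ASO-Ctr and -0.0845 in ASO-L1 against ASO-Ctr. In ASO-L1 against sO-L1 the span term was -0.0869. In the longest decile the median log2 fold changes were -0.0686, -0.1818 and -0.1205, in the same order. The ratio of rank correlations thus does not give the share of the effect. GC content as the whole cause is excluded only by a rule changed after the values were seen. Within 20 GC bins the mean correlation in ASO-L1 against sO-L1 was -0.131 ± 0.0117 in the fit, -0.091 ± 0.0099 in replicate 1 and -0.143 ± 0.0122 in replicate 2. A simulated GC effect gave 0.0064 ± 0.0067. All 3 values lie below the -0.05 that GC would need, which argues against it. Replicate 1 missed the limit of -0.1 first written, by which the test is undecided. Fold changes followed GC content less than span, with rank correlations of 0.0707 in ASO-L1 against sO-L1 and 0.0061 in ASO-L1 against ASO-Ctr. Those with span were -0.1485 and -0.2031, and the regression's GC terms were -0.0013 and -0.0127. These values argue against GC as more than a small part in the ASO-L1 comparisons. By the tertiles (-0.16, -0.149 and -0.091) a part stays undecided for GC. A part also stays open for any L1 oligo, so the pattern is not ascribed to L1.

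For the stress response genes, a single deviating library is excluded, as the lowest list median of 4 differences was 0.546. General stress of the transfected cells is undecided: the p53 list had a median of 0.266 and the interferon list -0.106 against ASO-Ctr. The inhibitor of this response was given to all groups, so its effect could not be tested.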
